A study of Homo sapiens with 16 samples.

How the data were processed

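Planar cultures of stem-cell-derived islets were made from HUES8, an established human embryonic stem cell line, and were sequenced as bulk total RNA. Each culture received either the solvent DMSO or 1 of 7 compounds from stage 5 of the differentiation through 7 days of stage 6, per the labels. There were 8 groups of 2 libraries, 16 in all, and every library carried the same batch label, batch 1. The groups were taken from the treatment label of each sample. The labels did not say whether the 2 libraries of a group came from separate differentiations, so the p-values measure the spread between these libraries, which may be partly technical.

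Per the labels' protocols, RNA from whole cultures was depleted of ribosomal RNA and made into libraries with the KAPA RNA HyperPrep kit with RiboErase and sequenced from both ends. Reads were checked with FastQC 0.11.8, trimmed with Trimmomatic 0.38, aligned with STAR 2.7.1a and processed with Picard 2.20.4 for duplicate marking and StringTie 2.0.4 for assembly, per the labels' protocols. The same protocols named featureCounts 1.6.0 or HTSeq for counting, and the submitters' processing notes named HTSeq and the GRCh38 genome. The annotation release, the strand setting and the treatment of multiply mapped and duplicate reads were not given in the sources used here. Antisense and overlapping genes and near-identical copies, such as tubulin genes, keratins and mitochondrial pseudogenes, are therefore uncertain, because reads could be split between them.

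The deposited values were raw counts of reads per gene, 62754 genes by 16 libraries, not normalised by the authors, and no column was left unmapped to a sample. Of these genes 20393 had no symbol and are given by identifier, and 44689 had at least 1 read. Library totals ran from 23294377 to 30701868 reads, and 31651 to 33185 genes had at least 1 read. A floor of 3 reads, below which a gene is not told from 0, corresponded to 0.0977 to 0.129 CPM (the reads of a gene scaled to the library total) across the libraries. This floor covers counting error only, since reads without molecular identifiers are not independent molecules.

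Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 8 groups, which left 24515 genes holding 99.92% of the reads, and libraries were scaled by TMM factors. All 16 libraries entered 1 fit with 1 coefficient per group and 8 residual degrees of freedom, so that the 7 comparisons with DMSO shared 1 estimate of the spread, and the common biological coefficient of variation was 0.1652. Each compound was compared with the 2 DMSO libraries by the two-sided quasi-likelihood F test with robust moderation. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. A joint test of the 7 coefficients asked whether any compound differed from DMSO. Log2 fold changes are given as compound minus DMSO with their standard errors (SE). Group levels with a standard deviation are TMM-normalised CPM, and ranges over libraries are plain CPM.

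The fit, its filter, 33 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 33 lists of each comparison, and again with the correlation estimated from the data. The lists covered endocrine cell types (beta cell identity, beta cell maturation, insulin processing and secretion, genes kept low in mature beta cells, alpha, delta, PP and epsilon, enterochromaffin-like and endocrine progenitor cells), other cell types (duct and pancreatic progenitor, acinar, mesenchyme, endothelium, neuron and neural crest, liver and gut, pluripotency) and responses (cell cycle, unfolded protein and integrated stress, oxidative stress, p53 targets, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, mitochondrially encoded, tubulin, FOXO targets and PI3K feedback, immediate-early and cAMP, YAP and cytoskeletal, interferon, NF-kB and inflammation, cytosolic ribosomal proteins, library and RNA quality, compound targets).

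By the rule, genes were named per comparison if they were among the 10 largest rising or 10 largest falling changes past the threshold, with a group mean of at least 1 CPM and both treated libraries on the same side of both DMSO libraries. Where fewer than 5 passed, the 5 genes with the smallest p were named, and up to 4 members per list past the threshold, a fixed panel of islet genes and the known targets of the compounds were added. List members given as examples without passing the threshold over all genes were those with the smallest p within their list, and they and the genes used to describe the make-up of the cultures were chosen after their values were seen. Some genes that the rule names are not reported here.

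Similarity of replicates was tested by the mean within-group Euclidean distance of log2 CPM (prior count 2) over the 2000 most variable genes, with group labels permuted 100000 times, one-sided. Because the 7 comparisons share the DMSO libraries, overlap and correlation between them were set beside 20 simulated sets of unchanged groups compared with the same controls. Replicates whose counts agree within sampling noise could be 1 library deposited again, but the chi-square per gene between replicates was 8.225 to 28.05 over the 8 groups, far above 1, so each library was counted separately. Alternatives were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no low-count filter, the replicate number as a block, only the 4 libraries compared, the other 6 compounds as the reference, and each replicate left out in turn, with the lone library left in a group taken to vary like the other groups.

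A correction for GC content was added after the data had been examined. Each library's deviation of log2 CPM from the gene mean was fitted against transcript GC content by a natural spline with 5 degrees of freedom over genes with a mean log2 CPM above 3, and the fitted curve entered the model as an offset. Transcript GC and coordinates came from GENCODE v29 on GRCh38, which gave a position for 95.28% of the tested genes. Also added were the endocrine score, the mean log2 CPM of CHGA, CHGB, SCG2, SCG3, PTPRN, INSM1, NEUROD1 and PAX6, as a covariate, and the lists against the other 6 compounds.

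The fit was tested on simulated counts of 24515 genes with 200 changed genes. For Colchicine against DMSO it recovered 8.955% of genes changed 1.5-fold, 35.82% of those changed 2-fold and 63.64% of those changed 4-fold, with 6 unchanged genes among 81 calls. For Rimonabant against DMSO with a simulated GC trend, 1499 of 1613 calls without the offset were unchanged genes, against 7 of 84 calls with it. The simulated trend was equal in both Rimonabant libraries and absent from DMSO. In the data it differed between the Rimonabant libraries, and the DMSO libraries deviated the other way. A smooth trend per library is what the offset is built to remove, so this result does not show how well it corrects the real data. By these shares, changes of 2-fold or less, and part of those of 4-fold, can stay below the threshold with 2 libraries per group.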

Results

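Total RNA from 16 cultures labelled as islets differentiated from HUES8 embryonic stem cells was measured, with 2 libraries for each of DMSO and 7 compounds. The compounds had been picked by a computational tool, DBSOMA, from a catalogue of transcriptional responses to drugs as ones that might act on beta-cell maturation, and the comparisons ask which genes each one moved. They were colchicine (10 nM, which blocks tubulin polymerisation), epirizole (2.5 uM, an anti-inflammatory drug), Ly-294002 (120 nM, an inhibitor of PI3 kinases), moxifloxacin (1.1 uM, a fluoroquinolone antibiotic), rottlerin (1.23 uM, used as an inhibitor of protein kinase C delta), vardenafil (125 nM, an inhibitor of phosphodiesterase 5) and rimonabant (125 nM, an antagonist of the cannabinoid receptor CNR1). These are unrelated structures at different doses, so no relation of structure to response was examined. Library totals ran from 23294377 reads in DMSO 1 to 30701868 in Ly-294002 1.

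Several transcripts of mature beta cells were scarce in every library. Of the 20 genes of the beta cell maturation list, 8 had a median under 1 CPM and 7 a median over 10 CPM. INS, the insulin gene (ENSG00000254647, chromosome 11, 2159779 to 2161341 on the minus strand of GRCh38, protein coding, overlapped on the same strand by the INS-IGF2 readthrough gene), had 17 to 180 reads, or 0.643 to 6.37 CPM. The readthrough gene had 0 or 1 read in each library, which does not tell whether reads shared by both genes were left uncounted. IAPP, the islet amyloid peptide, had at most 1 read in a library, MAFA, a transcription factor of mature beta cells, had 2 to 11, and G6PC2 had at most 7. UCN3 reached 0.696 CPM. The hormones glucagon (GCG) and somatostatin (SST) lay at 1.11 to 9.97 and 1.08 to 27.7 CPM. Broader markers were higher, with CHGA, a protein of secretory granules, at 31.6 to 315 CPM, PDX1, a pancreatic transcription factor, at 22.6 to 53.1 CPM, and NKX6-1 at 0.358 to 8.85 CPM. Whether the cultures had reached the labelled stage was not tested.

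The abundant transcripts included genes of epithelium, liver and extracellular matrix. AFP, alpha-fetoprotein, lay at 2690 to 6700 CPM, fibronectin (FN1) at 4690 to 6870 CPM, the fibrinogen chain FGB at a median of 1640 CPM and the mucin MUC16 at 1210 to 2560 CPM. CDH17, a cadherin of intestinal epithelium, had a median of 569 CPM, the ductal keratin KRT19 410 to 638 CPM and collagen COL3A1 443 to 1250 CPM. Of the 10 genes of the pluripotency list, 5 had a median under 1 CPM and 3 a median over 10 CPM. POU5F1 of this list was near the floor, with no more than 6 reads, and so was the endocrine progenitor factor NEUROG3, with no more than 4 reads. Exocrine trypsinogen PRSS1 lay at 0.195 to 1.44 CPM and the endothelial gene PECAM1 at 0.279 to 2.06 CPM.

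**Figure D1:**
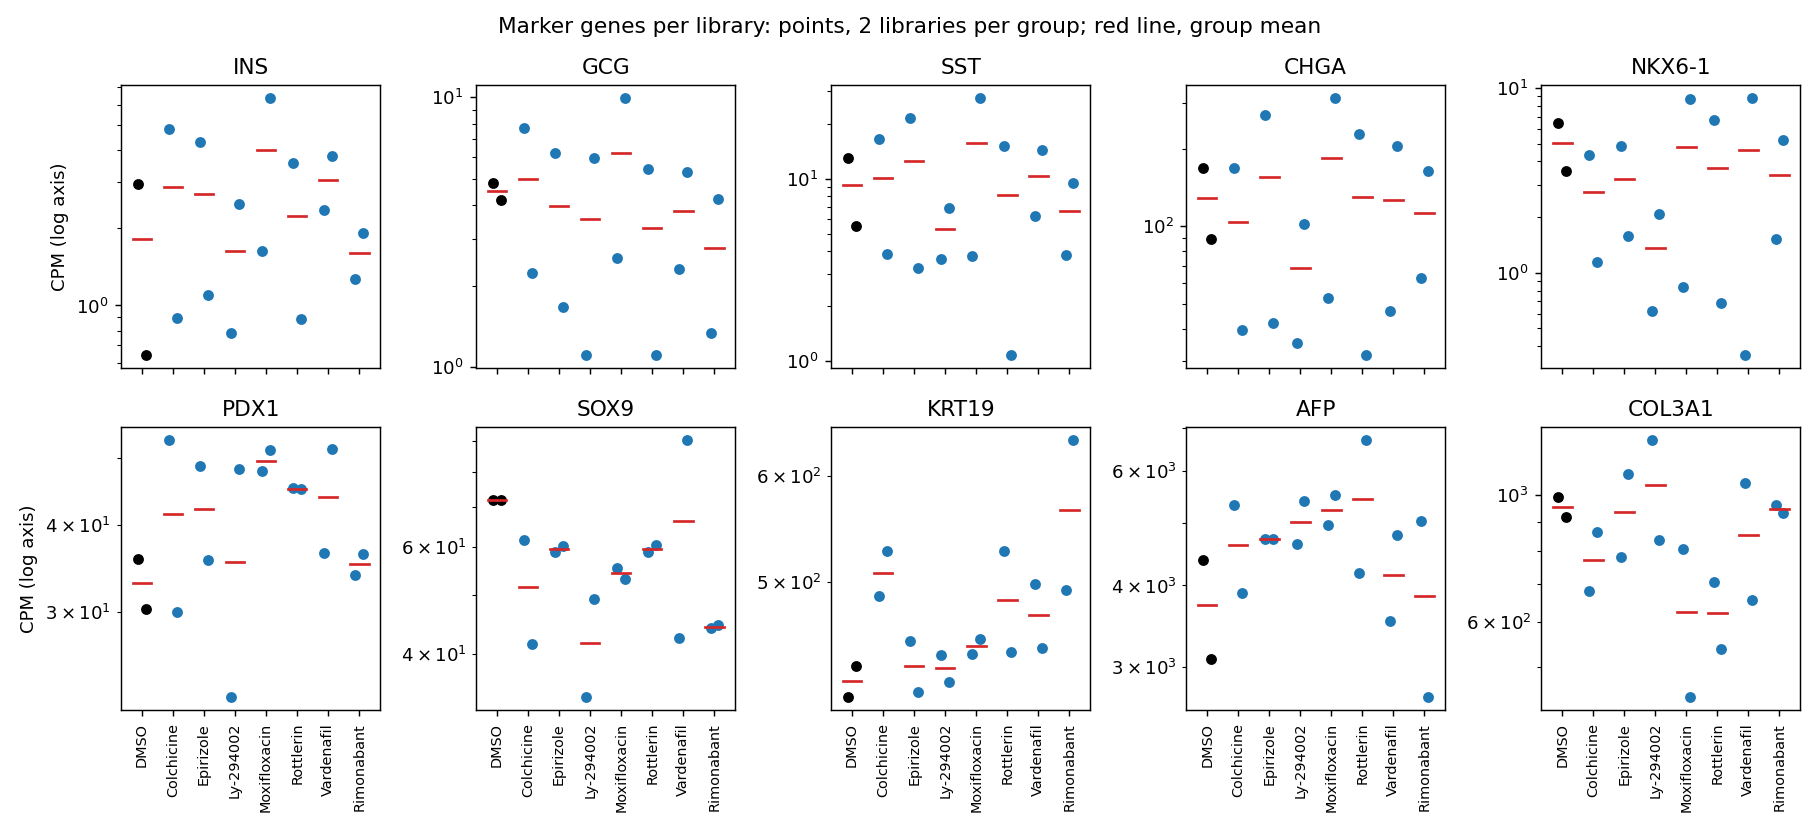
CPM on a log axis for 10 marker genes, with 1 point per library, 2 libraries per group (DMSO in black) and the group mean as a red line. The 2 libraries of a treatment often stood far apart for endocrine genes, as for CHGA in moxifloxacin at 52.36 and 315.4 CPM.

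Endocrine genes differed widely between the 2 libraries of a group. CHGA differed 1.888-fold between the 2 DMSO libraries and 7.199-fold between the 2 rottlerin libraries, the smallest and the largest of the 8 pairs. The first principal component held 19.63% of the variance and ran with the endocrine score over the 16 libraries (Spearman rho 0.8176, a description with no test, since the score was chosen after the data were seen) and, less closely, with the GC slope of the library (rho 0.5529). Libraries of 1 treatment were not found to lie closer together than libraries drawn at random: the mean distance was 56.8 within groups and 56.8 over all pairs (permutation test, one-sided p = 0.492, 2000 genes). Over all 24515 tested genes it was the smaller within groups, 94.26 against 96.06 (permutation test, one-sided p = 0.188). Only DMSO 1 had its own replicate as its nearest library, 1 of 16 libraries. Every group held 1 library with an endocrine score of at least 2.671 and 1 of at most 2.298. Distances within groups therefore always spanned this difference, while those of permuted groups need not. The test can thus miss a similarity of treatment.

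Colchicine raised CDKN1A, the cell cycle inhibitor p21 and a target of p53, from 50.4 ± 4.14 to 109.9 ± 5.90 CPM (SD, n = 2 each), a log2 change of 1.13 (SE 0.10, adjusted p = 0.000297 by edgeR). CDKN1A (ENSG00000124762) lies on chromosome 6, 36676460 to 36687339, plus strand, and is overlapped on the other strand by DINOL. BAX, a p53 target that promotes apoptosis, rose by 0.73 (SE 0.12, adjusted p = 0.0401), and so did COL2A1, a cartilage collagen, by 0.83 to 983 ± 35.8 CPM (adjusted p = 0.00993), the peroxidase PRDX1 by 0.52 and the actin crosslinker filamin A (FLNA) by 0.53. Other large rises were TMEM160 at 1.80, UBL5 at 0.86, CYBA at 0.83, MZT2B at 0.83, NAGLU at 0.82, YIF1A at 0.78 and MID1IP1 at 0.73. The largest falls were in LAMA4, a laminin chain, from 6.09 ± 0.779 to 0.640 ± 0.0207 CPM (log2 change −3.24, SE 0.48, adjusted p = 0.0401), ADAMTSL1 (−2.05), SHISA2 (−1.92), the skeletal transcription factor RUNX2 (−1.70), the sarcoglycan SGCD (−1.68), GNAL (−1.19), the calcium channel CACNA1C (−0.99), COL19A1 (−0.94), the inositol transporter SLC5A3 (−0.82) and SP4 (−0.72).

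In all, 48 genes passed the threshold with colchicine, 31 higher and 17 lower, among 4297 with an unadjusted p under 0.05, against 1226 by chance. Of the p53 target list, 14 of 15 members lay above DMSO with a median log2 change of 0.31, and 2 passed over all genes and 9 adjusted over the list alone, among them FDXR (0.85, SE 0.21) and PHLDA3 (0.68, SE 0.18). This list rose in camera (adjusted p = 1.82e-09) and also held with the correlation estimated (adjusted p = 0.0492 with an estimated correlation), but not when the GC offset was used as well (adjusted p = 0.125 with an estimated correlation). The tubulin list rose as well, with 12 of 12 members above DMSO, a median of 0.37 and 6 members adjusted over the list alone (TUBA1C 0.51, TUBB2A 0.71; median 0.16 and 1 member with the GC offset), as did cholesterol synthesis (median 0.19), liver and gut (0.22, with deviations of 0.50 in Colchicine 1 and 0.10 in Colchicine 2, whose endocrine scores were 3.607 and 1.404, APOA1 at 0.87 and CDX2 at 0.67), oxidative phosphorylation (0.21) and the YAP and cytoskeletal list (0.08). Mesenchyme (median −0.70, 16 of 19 below DMSO, with CDH11 at −1.40 and POSTN at −1.15), hypoxia and glycolysis (−0.58, with PGK1 at −0.80) and mitochondrially encoded transcripts (−0.57, 13 of 13 below) fell. The cholesterol rise and the mitochondrial fall were larger in Colchicine 1 (median deviations 0.25 and −0.83) than in Colchicine 2 (0.08 and −0.36). Apart from the p53 targets, these 8 lists were not called with the correlation estimated (adjusted p = 0.26 to 0.715 with an estimated correlation). CDKN1A was the 1 gene left with the GC offset (0.93, adjusted p = 0.000461), and the YAP list was lost (adjusted p = 0.243). The count was 2 without Colchicine 1 and 1 without Colchicine 2, DMSO 1 or DMSO 2, and the transcripts called up had a median GC of 58.89% against 44.7% for those called down.

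**Figure D2:**
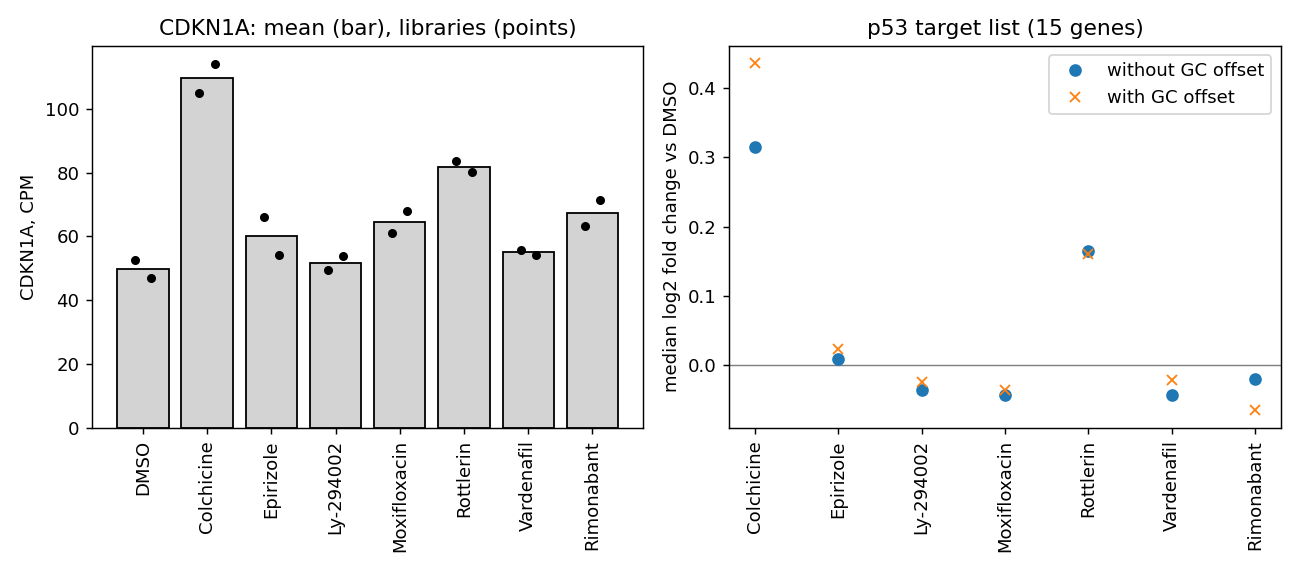
Left, CDKN1A in CPM, with bars for the group mean and points for the 2 libraries of each group. Right, the median log2 fold change against DMSO of the 15 p53 targets per compound, without (circles) and with (crosses) the GC offset. Colchicine was highest in both panels, with a list median of 0.31 without the offset and 0.44 with it.

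Rottlerin raised 2 genes past the threshold, CEBPA and CDKN1A. CEBPA (ENSG00000245848, chromosome 19, 33299934 to 33302564, minus strand), a transcription factor of liver and fat cells, went from 25.5 ± 2.12 to 56.5 ± 11.5 CPM (log2 change 1.15, SE 0.15, adjusted p = 0.0295 by edgeR), and CDKN1A from 50.4 ± 4.14 to 82.4 ± 1.54 CPM (0.71, SE 0.10, adjusted p = 0.0484). The next genes by p were not past it: ZNF721 (−0.55), SHISA2 (−2.17) and TGM2 (1.12), each with an adjusted p of 0.0591. Liver and gut genes lay above DMSO for 14 of 17 members with a median of 0.46, and 6 rose adjusted over the list alone, such as APOC3 (1.36, SE 0.33), albumin ALB (1.22, SE 0.29), APOA1 (0.95) and CDX1 (0.77). The median log2 deviation of the list from the DMSO mean was 0.25 in Rottlerin 1 and 0.65 in Rottlerin 2, which had the lowest endocrine score of the 16 libraries (1.145, against 3.65 in Rottlerin 1). Cholesterol synthesis genes lay above DMSO for 17 of 18 members (median 0.30), with 10 adjusted over the list alone, led by CYP51A1 (1.20, SE 0.21) and MVD (0.67). Both lists rose in camera (adjusted p = 1.22e-05 and 4.23e-11) and neither with the correlation estimated (adjusted p = 0.241 and 0.241 with an estimated correlation).

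Of the other lists under rottlerin, tubulin (median 0.34), oxidative phosphorylation (0.20), p53 targets (0.16, with 3 adjusted over the list alone) and the YAP list (0.12) rose. The last 2 lay mostly in Rottlerin 2, with median deviations of 0.26 for both against 0.06 and −0.06 in Rottlerin 1. Mitochondrially encoded transcripts (−0.64, with 12 adjusted over the list alone and MT-ND6 at −1.17), mesenchyme (−0.63, POSTN −1.33), cell cycle (−0.22) and immediate-early genes (−0.18, with −0.10 in Rottlerin 1 and −0.37 in Rottlerin 2, EGR1 −0.54) fell. With the correlation estimated, none of the 10 lists was called (adjusted p = 0.241 to 0.746 with an estimated correlation), and the YAP list was also lost with the GC offset (adjusted p = 0.46). The 2 genes stood among 3623 with an unadjusted p under 0.05 (1226 by chance), and DESeq2 called 492. With the GC offset there were 0 in edgeR, where CEBPA changed by 0.79 and CDKN1A by 0.51 (both adjusted p = 0.105). The count was 5 without Rottlerin 1 and 0 without Rottlerin 2, DMSO 1 or DMSO 2.

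Rimonabant gave 1913 genes past the threshold, 1234 higher and 679 lower. Among the largest rises, all at low levels, the keratin KRT5 (ENSG00000186081, chromosome 12, 52514575 to 52520687, minus strand) went from 0.255 ± 0.237 to 6.61 ± 3.50 CPM (log2 change 4.64, SE 0.98, adjusted p = 0.0226 by edgeR) and KRT6A from 0.159 ± 0.101 to 2.67 ± 0.0262 CPM (4.003, SE 0.71, adjusted p = 0.012). KRT16 (3.30), GJA5 (3.30), SLC16A11 (2.996), KRT1 (2.72), KCNJ4 (2.51), TMEM160 (2.02), the chemokine CCL5 (2.01) and the actin pseudogene ACTG1P20 (1.99) followed. Among the falls with the largest size were the mitochondrial pseudogene MTATP6P19 (−2.31), CHD9NB (−2.19), CDKN2B-AS1 (−2.07), TLE1-DT (−1.81), LRRN3 (−1.76), the chemokine CCL20 (−1.73), the synaptotagmin SYT4 (−1.72), ITCH-IT1 (−1.68) and the dopamine receptor DRD1 (−1.61), all under 10 CPM. Abundant genes moved less, such as FLNA (0.52, to 1905 ± 65.8 CPM), KRT19 (0.37, but −0.11 with the GC offset), CLDN4 (0.69), KRT7 (0.99), TUBA1B (0.46) and MALAT1 (−0.45).

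Mitochondrially encoded transcripts fell in rimonabant, with 13 of 13 below DMSO, a median of −0.79 and 4 past the threshold over all genes (MT-ND6 −1.30, MT-ND2 −1.08, MT-ATP8 −1.58, MT-ND5 −0.75), and 13 adjusted over the list alone. The median log2 deviation from the DMSO mean was −0.43 in Rimonabant 1 and −1.26 in Rimonabant 2. Tubulins rose (median 0.46, 12 of 12 above, 6 past the threshold and 11 adjusted over the list alone), as did cholesterol synthesis (0.17, with 6 past the threshold, such as MVD at 0.78 and CYP51A1 at 1.20) and cytosolic ribosomal proteins (0.15, RPS19 0.53), while hypoxia and glycolysis fell (−0.35). The ribosomal rise and the hypoxia fall were larger in Rimonabant 2 (0.20 and −0.47) than in Rimonabant 1 (0.08 and −0.22). None of the 5 was called with the correlation estimated (adjusted p = 0.527 to 0.904 with an estimated correlation), and the ribosomal proteins were lost with the GC offset (adjusted p = 0.152).

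GC content separated the genes that rimonabant moved up from those it moved down, with a median transcript GC of 61.06% for the first and 38.64% for the second, against 47.8% of all tested genes. Across 23352 genes, which are not independent replicates, the log2 change ran with GC (Spearman rho 0.5743). Rimonabant 2 stood apart from the rest in this measure, with a difference of 0.71 in log2 units between the highest-GC and lowest-GC genes, while the DMSO libraries lay at −0.32 and −0.37. With the GC offset 0 genes passed in edgeR, with 2322 at an unadjusted p under 0.05, whereas DESeq2 without the offset called 2298. The median size of the change of the 1913 genes went from 0.54 (median SE 0.13) to 0.17 (median SE 0.10), and 1710 kept their sign. Without Rimonabant 1 the count was 3913, and without Rimonabant 2, DMSO 1 or DMSO 2 it was 0. The list count was 3 without Rimonabant 1 and 2 without DMSO 2.

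**Figure D3:**
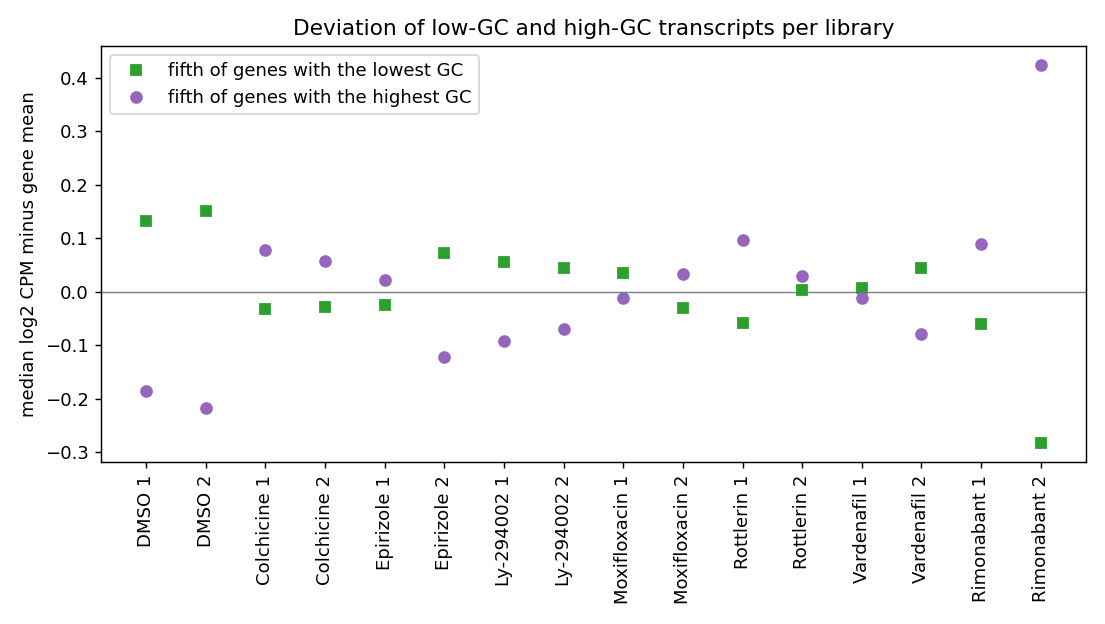
Median deviation of log2 CPM from the gene mean for the lowest-GC (squares) and highest-GC (circles) quintile of expressed genes, per library. The DMSO libraries deviate one way (highest-GC genes at −0.19 and −0.22) and Rimonabant 2 the other way (0.42).

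With moxifloxacin, mesenchyme and cell cycle lists lay lower and liver and gut genes higher, with no single gene past the threshold. All 22 cell cycle genes lay below DMSO (median −0.42, adjusted p = 5.16e-06), such as PCNA (−0.67, SE 0.20), and 16 of 19 mesenchyme genes (median −0.64, adjusted p = 1.53e-06). Both falls were mostly in Moxifloxacin 2, with a median log2 deviation from the DMSO mean of −0.72 for cell cycle (−0.15 in Moxifloxacin 1) and −1.02 for mesenchyme (−0.25). That library had the highest endocrine score of the 16 (4.185, against 1.847 in Moxifloxacin 1), and the beta cell identity list deviated by 0.68 in it and by −0.27 in Moxifloxacin 1. Immediate-early genes fell (median −0.23, with 6 members adjusted over the list alone, such as EGR1 at −0.59 and EGR3 at −1.05), as did mitochondrially encoded transcripts (−0.49), hypoxia and glycolysis (−0.43) and the unfolded protein and integrated stress list (−0.14, ATF3 −0.67). Hypoxia and glycolysis also fell mostly in Moxifloxacin 2 (−0.68, against −0.24 in Moxifloxacin 1). Liver and gut (0.32, CDX2 0.57, CDX1 0.66), tubulin (0.33, TUBB3 0.68), cholesterol synthesis (0.13) and oxidative phosphorylation (0.12) rose. None of the 10 lists was called with the correlation estimated (adjusted p = 0.338 to 0.612 with an estimated correlation). The genes with the smallest p were the phosphodiesterase PDE10A (−0.61, SE 0.09, adjusted p = 0.248), UBL5 (0.77), RHOC (0.55), RAMP1 (0.75) and SELENON (0.51), the last 4 with an adjusted p of 0.289. In edgeR 0 genes passed and 2908 had an unadjusted p under 0.05, while DESeq2 called 44.

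Epirizole gave 0 genes past the threshold in edgeR and 0 in DESeq2, with 1289 at an unadjusted p under 0.05 and 1226 by chance. The identifier ENSG00000262228 (1.27), TNS4 (3.55, at 0.526 ± 0.119 CPM), SELENON (0.39), PDE10A (−0.39) and SPATA12 (3.45) had the smallest p, each with an adjusted p of 0.901. Tubulins (median 0.29, 12 of 12 above DMSO, TUBB3 0.54) and cholesterol synthesis (0.11) rose. Immediate-early genes (−0.17, EGR1 −0.43), hypoxia and glycolysis (−0.29), mitochondrially encoded transcripts (−0.24), cell cycle (−0.18) and the unfolded protein and integrated stress list (−0.14, ATF3 −0.46) fell. Of these, 4 lay mostly in Epirizole 1, with median deviations from the DMSO mean of −0.59 for hypoxia and glycolysis (−0.05 in Epirizole 2), −0.48 for cell cycle (0.04), −0.38 for mitochondrially encoded transcripts (−0.13) and −0.22 for the stress list (−0.04). That library had an endocrine score of 3.971, against 1.655 in Epirizole 2, and the beta cell identity list deviated by 0.37 in it and by −0.44 in Epirizole 2. None of the 7 was called with the correlation estimated (adjusted p = 0.337 to 0.99 with an estimated correlation), and without DMSO 2 there were 3.

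With Ly-294002, genes of insulin processing and secretion (22 of 25 below DMSO, median −0.32, adjusted p = 0.0352) and of duct and pancreatic progenitors (−0.16, SOX9 −0.81, SPP1 −0.65) lay lower. The first fall was mostly in Ly-294002 1 (median log2 deviation from the DMSO mean −0.59, against −0.15 in Ly-294002 2), which also had the lower endocrine score (1.244 against 2.671). The insulin processing and secretion list was not called against the other 6 compounds (adjusted p = 0.0931 by camera). The duct and pancreatic progenitor fall also lay mostly in Ly-294002 1 (−0.20, against −0.07 in Ly-294002 2). The stress list (16 of 19 below, median −0.17, ATF3 −0.64), immediate-early genes (−0.27, EGR3 −0.90, EGR1 −0.46), hypoxia and glycolysis (−0.33, with −0.12 in Ly-294002 1 and −0.47 in Ly-294002 2) and mitochondrially encoded transcripts (−0.25) fell. Tubulins (0.25, with 0.16 in Ly-294002 1 and 0.36 in Ly-294002 2) and the YAP list (0.08, with 0.15 and 0.03) rose. None of the 8 was called with the correlation estimated (adjusted p = 0.211 to 0.827 with an estimated correlation). The YAP list was lost with the GC offset (adjusted p = 0.199), and without Ly-294002 1 there were 5 lists. In edgeR 0 genes passed and 1150 had an unadjusted p under 0.05, and DESeq2 called 0. PRSS1 (−2.69, SE 0.50), ENSG00000262228 (1.53), ATF3 (−0.64) and the phospholipase PLCB1 (−0.58), each with an adjusted p of 0.762, and ENSG00000237852 (−3.01, adjusted p = 0.969) had the smallest p. Its list of FOXO targets and PI3K feedback was not called in any comparison.

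With vardenafil, mesenchyme genes (18 of 19 below DMSO, median −0.37, POSTN −0.98, DCN −1.32), mitochondrially encoded transcripts (−0.29) and immediate-early genes (−0.30, EGR1 −0.39) lay lower, and cytosolic ribosomal proteins (0.09, RPS14 0.28) higher. The mesenchyme fall was mostly in Vardenafil 2 (median deviation −0.61, against −0.13 in Vardenafil 1) and the mitochondrial one mostly in Vardenafil 1 (−0.46, against −0.14 in Vardenafil 2). The ribosomal rise also lay mostly in Vardenafil 1 (0.14, against 0.03 in Vardenafil 2). The endocrine score was 3.64 in Vardenafil 2 and 1.691 in Vardenafil 1, and the beta cell identity list deviated by 0.48 and −0.20. None of the 4 was called with the correlation estimated (adjusted p = 0.761 to 0.847 with an estimated correlation), and there were 10 lists without DMSO 1 and 2 without DMSO 2. In edgeR 0 genes passed and 1280 had an unadjusted p under 0.05, while DESeq2 called 2. LAMA4 (−2.58, SE 0.46), the signal recognition particle RNA RN7SL3 (0.59), VPS51 (0.56), KRT6A (3.39, at 1.75 ± 0.236 CPM) and FMOD (−3.62) had the smallest p, each with an adjusted p of 0.89.

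**Figure D4:**
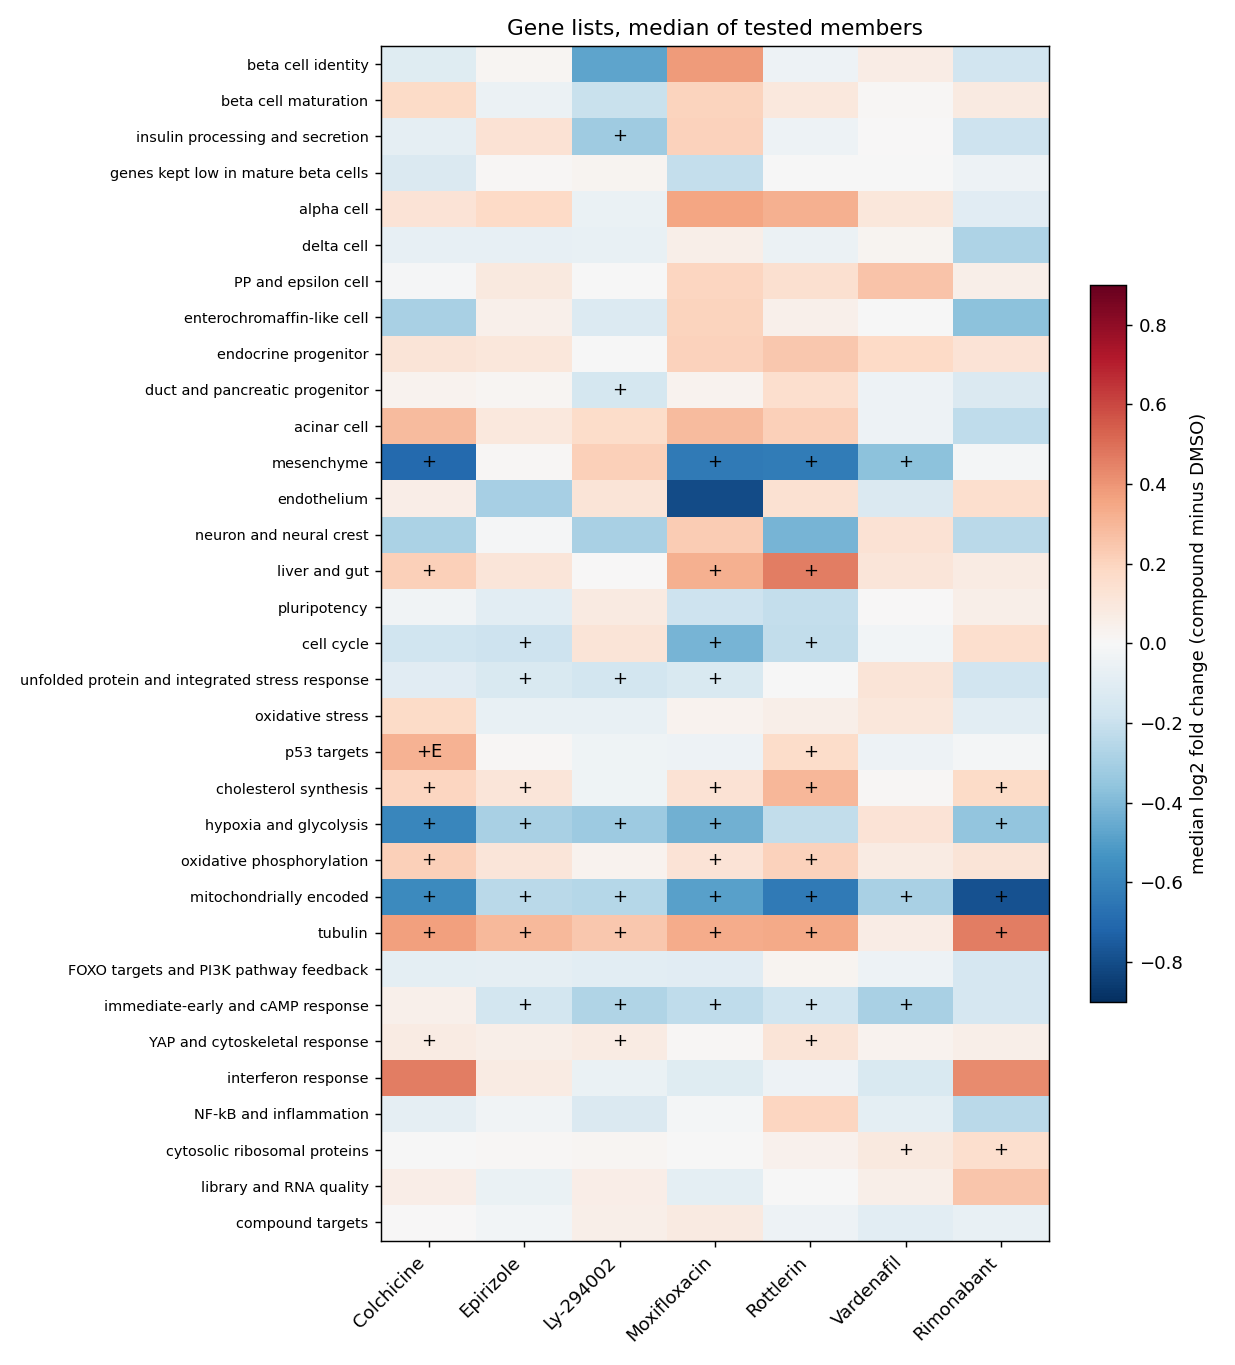
Median log2 fold change of the tested members of each gene list (vertical axis), per compound against DMSO (horizontal axis), in colour. A plus marks lists called with the preset correlation, and E the 1 also called with the correlation estimated, the p53 targets in colchicine (median 0.31).

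None of the islet genes INS, CHGA, PDX1, NKX6-1, GCG, SST and UCN3 passed the threshold with any compound. The log2 change of INS lay between −0.22 and 1.13 over the 7 compounds, with standard errors of 1.11 to 1.15 and a lowest adjusted p of 0.729. That of CHGA lay between −0.93 and 0.48 (lowest adjusted p = 0.921), of PDX1 between 0.03 and 0.55 (0.561), of NKX6-1 between −1.93 and −0.10 (0.829), of GCG between −0.76 and 0.44 (0.752), of SST between −0.84 and 0.73 (0.867) and of UCN3 between −1.95 and 1.03 (0.711). IAPP, MAFA and G6PC2 had too few reads to be tested. The beta cell identity list had medians from −0.48 (Ly-294002) to 0.38 (moxifloxacin) and beta cell maturation from −0.20 to 0.20, and neither was called against DMSO. Against the other 6 compounds, beta cell identity was lower in Ly-294002 (−0.43, adjusted p = 0.0175 by camera, and 0.583 with an estimated correlation). It was higher in moxifloxacin (0.35, adjusted p = 0.00741 by camera, and 0.542 with an estimated correlation). From the DMSO mean it deviated by −0.59 in Ly-294002 1 and −0.03 in Ly-294002 2. The 1 member of the 2 lists past the threshold over all genes was SYT4 in rimonabant (−1.72, adjusted p = 0.0364), and not with the GC offset (adjusted p = 0.369). With these standard errors a change of 2-fold in the hormones was not detectable.

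The remaining lists were called in none of the 7 comparisons. Over all 33 lists, median, mean and test direction differed in sign for 4 to 12 lists per compound, none of them called. Their medians ran from −0.21 to 0.02 for genes kept low in mature beta cells, −0.10 to 0.36 for alpha, −0.28 to 0.05 for delta, −0.01 to 0.26 for PP and epsilon, −0.37 to 0.20 for enterochromaffin-like and −0.0027 to 0.24 for endocrine progenitor cells. They ran from −0.23 to 0.29 for acinar cells, −0.80 to 0.15 for endothelium, −0.42 to 0.23 for neuron and neural crest and −0.21 to 0.08 for pluripotency. For responses the ranges were −0.10 to 0.17 for oxidative stress, −0.15 to 0.03 for FOXO targets, −0.14 to 0.46 for interferon, −0.24 to 0.19 for NF-kB and inflammation, −0.09 to 0.25 for library and RNA quality and −0.10 to 0.08 for compound targets. With the GC offset 3 calls appeared among them, with beta cell identity in Ly-294002 at −0.48 (adjusted p = 0.0154), endothelium in moxifloxacin at −0.88 (adjusted p = 0.0176) and interferon in colchicine at 0.45 (adjusted p = 0.0419). None of these held with the correlation estimated (adjusted p = 0.647, 0.342 and 0.522 with an estimated correlation). Among the compounds' targets, PDE5A, the target of vardenafil, lay at 45.2 to 109 CPM, the receptor CNR1 at 7.14 to 15.8 CPM, and the cyclooxygenase PTGS1 had at most 6 reads and was not tested.

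Mitochondrially encoded transcripts fell in 7 of 7 comparisons, tubulins rose in 6, and hypoxia and glycolysis and immediate-early genes each fell in 5, all without holding when the correlation was estimated (lowest adjusted p = 0.316, 0.211, 0.516 and 0.227 with an estimated correlation). With the GC offset the tubulin medians of these 6 compounds ran from 0.13 to 0.22 (0.25 to 0.46 without it), still called, and the immediate-early medians of these 5 from −0.40 to −0.32 (−0.30 to −0.17 without it). Measured against the other 6 compounds in place of DMSO, tubulin was called in none of the 6. In vardenafil, where it was not called against DMSO, it was lower (−0.24, adjusted p = 5.28e-07 by camera, and 0.381 with an estimated correlation). The mitochondrial list was higher rather than lower in epirizole, Ly-294002 and vardenafil (0.25, 0.22 and 0.20, adjusted p = 9.28e-07, 0.000404 and 0.0018 by camera, and 0.871, 0.524 and 0.768 with an estimated correlation). Hypoxia and glycolysis was then not called in epirizole, Ly-294002 or rimonabant (adjusted p = 0.896, 0.947 and 0.383) and was higher in vardenafil (0.48, adjusted p = 3.54e-09, and 0.381 with an estimated correlation). Immediate-early genes were not called in epirizole, rottlerin or vardenafil (adjusted p = 0.743, 0.858 and 0.383) and were higher in colchicine (0.17, adjusted p = 1.64e-05, and 0.404 with an estimated correlation). Over all lists called against DMSO, those called in the same direction against the other 6 compounds numbered 5 of 9 for colchicine, 0 of 7 for epirizole, 3 of 8 for Ly-294002, 4 of 10 for moxifloxacin, 7 of 10 for rottlerin, 0 of 4 for vardenafil and 2 of 5 for rimonabant. The 7 comparisons used the same 2 DMSO libraries. In the joint test of any compound, CDKN1A was the 1 gene past the threshold (adjusted p = 0.00191 by edgeR). Colchicine and rimonabant shared 24 genes called higher and 9 called lower, against 1.56 and 0.4709 for independent lists. Simulated unchanged groups shared a mean of 0.05, but these hold no effects, so this value says little about lists of 48 and 1913 genes. With the GC offset, where rimonabant had 0 calls, 0 genes were shared. Across 11248 genes, the correlation of log2 changes between 2 compounds had a median of 0.6865 over 21 pairs (0.4093 to 0.8512), where unchanged groups compared with the same controls gave 0.5037. The median covariance was 0.0406 against 0.0200 in the simulation, and 0.0206 with the GC offset. With the GC offset the median correlation was 0.5514. A split of the controls would leave 1 library on each side and was not made. Part of the excess without the offset may therefore come from the shared DMSO libraries, if they deviate by more than the simulated spread.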

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

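The GC offset, its combinations, the endocrine covariate and the lists against the other 6 compounds were chosen after the results were seen, and the other settings before. CDKN1A in colchicine kept its direction and passed the threshold under every setting run, and it was the 1 of the 22 genes named for colchicine to do so with the GC offset, against the other 6 compounds and in each fit without 1 library. Of 59 named for rimonabant, none passed with the GC offset or against the other 6 compounds. KRT19 (−0.11) and ARHGEF17 (−0.0405) in rimonabant reversed with the GC offset, and CDKN1A in rimonabant (−0.0475) against the other 6 compounds. Depth limits genes near the floor of 3 reads, such as IAPP, and the spread between the 2 libraries per group limits the rest, the hormones included. The cause was not tested for any change below except where a setting tests fewer samples or other genes.

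For colchicine the count of genes was 150 with DESeq2 size factors, 1568 with no low-count filter, 718 with DESeq2, 259 with only the 4 libraries compared, 4 against the other 6 compounds, 1 with the GC offset, 10 with both of these, 1603 with the endocrine covariate, and 1 to 2 without 1 library. For rottlerin it was 1076 with no filter, 492 with DESeq2, 71 with 4 libraries, 15 against the other 6, 0 with the GC offset, 15 with both, 916 with the covariate and 0 to 5 without 1 library. For rimonabant it was 200 with 4 libraries, 0 against the other 6, 0 with the GC offset, 0 with both, 3638 with the covariate and 0 to 3913 without 1 library. For moxifloxacin it was 742 with no filter, 44 with DESeq2, 9 with 4 libraries and 22 with the covariate. For vardenafil these were 113, 2, 7 and 1. No filter gave 33 for epirizole and 169 for Ly-294002, and 4 libraries gave 5 for Ly-294002. The joint test gave 3022 with no filter and 1080 with DESeq2. Genes on one side of DMSO in all 14 treated libraries numbered 725 with the GC offset, from 1748. Shared calls numbered 108 with DESeq2 size factors and 0 with the GC offset. Replicate similarity had p = 0.188 over all tested genes, with the distance within groups now the smaller (permutation test). The cause was not tested.

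The lists called fell to 1 for colchicine and to 0 for the other 6 compounds with the estimated correlation, and to 0 for colchicine as well with the GC offset added. Against the other 6 compounds they numbered 3 for epirizole, 15 for Ly-294002 and 7 for vardenafil, of which 0, 3 and 0 were called in the same direction against DMSO, and with the GC offset 12 for rimonabant. Without 1 library they ran from 3 to 8 for epirizole, 5 to 12 for Ly-294002, 2 to 10 for vardenafil and 2 to 7 for rimonabant. The cause was not tested.

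The replicate numbers were not found to pair the libraries. Over 28 pairs of groups the correlation of same-numbered deviations ran from −0.2825 to 0.2259, with a median of −0.0325. Every group held 1 library with an endocrine score of at least 2.671 and 1 of at most 2.298. The higher was replicate 1 in DMSO, colchicine, epirizole and rottlerin, and replicate 2 in the rest. The highest correlation joined moxifloxacin and vardenafil, numbered alike by score, and the lowest epirizole and moxifloxacin, numbered oppositely. A pairing by score is not excluded, and a block by replicate number cannot take it up. With the replicate number as a block the counts were 5 for colchicine, 1090 for rimonabant and 2 for rottlerin, of which 4, 1086 and 1 were also called without it (CDKN1A in rottlerin had an adjusted p of 0.0729), and shared calls 5. With the block and the GC offset together they were 1, 0 and 0. The block changed no other count of genes or lists by more than 1.5 times.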

Other observations

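The test of the endocrine share, the GC offset and the comparison of lists with the other 6 compounds were chosen after the results were seen, and the genes in this part were chosen after their values were seen. Measured against the 12 libraries of the other 6 compounds rather than DMSO, rottlerin raised 15 genes (log2 change 0.63 to 2.44, SE 0.10 to 0.35, adjusted p = 0.0118 to 0.0493 by edgeR), and the same 15 passed with the GC offset. They included the fatty acid binding protein FABP1 (1.34, SE 0.17), lactase LCT (1.51, SE 0.20), the retinol binding protein RBP2 (2.44), the chloride exchanger SLC26A3 (1.39), the mucin MUC17 (2.27), the trefoil peptide TFF2 (1.23), ACSL5 (1.77), CEACAM1 (1.35), TSPAN8 (1.05) and S100P (1.21). CEBPA (0.78), AADACL3 (2.16), HSD3B1 (2.23), LINC01559 (1.47) and ACER2 (0.63) made up the rest. Both rottlerin libraries lay above all 12 others for 14 of the 15 genes and above both DMSO libraries for 15, but against DMSO alone 1 passed the threshold. The liver and gut list, fixed beforehand and sharing none of these genes, lay higher against the other 6 compounds (median 0.33, adjusted p = 1.76e-06 by camera), though not with the correlation estimated (adjusted p = 0.163 with an estimated correlation).

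Colchicine raised 4 genes against the other 6 compounds: CDKN1A (0.82, SE 0.07, adjusted p = 0.000205), DDB2 (0.61, SE 0.09, adjusted p = 0.0349), PURPL (0.53, SE 0.07, adjusted p = 0.025) and MYADM (0.41, SE 0.06, adjusted p = 0.0438), each in both libraries above all 12 others. DDB2, a DNA damage recognition protein, and PURPL, a long noncoding RNA, are known targets of p53. Against DMSO alone PURPL did not pass (0.28, adjusted p = 0.151), and both DMSO libraries lay above those 12 as well, while the others passed. All 4 passed with the GC offset against the other 6 compounds, where 10 genes passed in all. The p53 target list held in this comparison with the correlation estimated as well (median 0.39, adjusted p = 0.00193 with an estimated correlation).

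The transcription factors GATA3, TFAP2A and TP63 lay at 35.2 to 106, 50.8 to 154 and 17.2 to 57.7 CPM, and the hormone chain CGA at 0.215 to 16.4 CPM. All 14 treated libraries lay above both DMSO libraries for 868 genes and below both for 880, 7.13% of the tested genes against 1.667% by chance. The first had a median transcript GC of 59.78% and the second of 39.94%, against 47.8% of all tested genes, and with the GC offset the counts were 412 and 313 (2.957%). RN7SL1 (mean log2 change over the compounds 0.92) and PCSK1N (0.82) were among those above, and MTATP6P1 (−0.81), EGR3 (−0.74) and MT-ND2 (−0.68) among those below.

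The 1913 calls of rimonabant ran with GC content across genes (Spearman rho 0.5743), and 0 were left with a GC offset per library because the changes shrank from a median size of 0.54 (SE 0.13) to 0.17 (SE 0.10). Against the other 6 compounds there were 0 calls, as a deviation of the 2 DMSO libraries would give. Without Rimonabant 1, which leaves Rimonabant 2, there were 3913, and without Rimonabant 2 there were 0, as a single deviating library would give, but there were also 0 without DMSO 1 or DMSO 2, so the 0 is not specific to Rimonabant 2. A GC trend that sets Rimonabant 2 and the DMSO libraries apart in opposite directions may therefore account for most of these calls. The difference between highest-GC and lowest-GC genes was 0.15 in Rimonabant 1, near that of Rottlerin 1 (0.16), against 0.71 in Rimonabant 2. The size seen in Rimonabant 2 was thus not repeated in the other library of the compound. An effect of the compound on GC-rich transcripts stays open and was not tested, since the libraries cannot tell it from a library effect.

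Tubulins above DMSO and mitochondrial transcripts below it in most compounds may come from the same GC trend or from the DMSO libraries. With the GC offset the median over the 7 compounds kept 78.37% of its size for the mitochondrial list and 49.65% for tubulin, which argues against the trend as the whole cause for the first, while for the second the cause cannot be told apart. Against the other 6 compounds, 2 of 14 tests of these lists were called with the sign seen against DMSO, both for mitochondrial transcripts (in rottlerin and rimonabant, adjusted p = 0.675 and 0.811 with an estimated correlation). In either direction 5 mitochondrial tests were called, and 1 of tubulin, lower in vardenafil (−0.24, adjusted p = 5.28e-07 by camera, and 0.381 with an estimated correlation). These counts lie between what a deviation of the DMSO libraries would give and what it would exclude. A response to the solvent control or to the compounds in common stays open.

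Endocrine genes differed between the replicates of every group, by 1.019 to 2.505 in the endocrine score. A different share of endocrine cells in each culture is a candidate explanation: over the 8 pairs, the differences of 25 genes of insulin processing and secretion ran together with a median pairwise Spearman rho of 0.4881, above the highest of 1000 random lists (0.1905) but under the bound of 0.5 set for it, so it stays open. This bound was set after the results were seen. The 8 genes of the endocrine score ran together with a median pairwise rho of 0.9524, but they were chosen after the data were seen. CHGA, CHGB, SCG2, SCG3 and PTPRN belong both to the list and to the endocrine score. The random lists were drawn from all expressed genes, so other sets of genes that vary together could also exceed them. Library depth was not found to run with the difference (Spearman rho −0.3095, exact permutation p = 0.462, Pearson r −0.4752, exact permutation p = 0.241, and −0.4201 without the 2 pairs farthest from the median). The rho lay under the bound set for depth, but 8 pairs are too few to exclude a relation, so depth stays open as well. In this family 2 relations were computed.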
